A study of uncultured soil microorganism with 15 samples.

How the data were processed

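The deposited files hold an intensity table of 82958 probes and a normalized table of 75109 probes for the same 15 arrays, with gene name, category, subcategory, organism and lineage of each probe. Per the file headers the values of the normalized table are scores after a relative abundance and natural log step, and the deposited values of the intensity table are intensity per probe with blanks where a probe was not called. How the authors corrected background and scaled the intensity is not given in the sources used here, and neither the scan order nor the slide of an array is given.

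The design, fixed before the files were read, assumed linear values in the normalized table. The values showed that each deposited score is the natural log of the intensity over the mean natural log intensity of its array, with the values dropped where a probe was listed on only 1 of the 3 arrays of a group. Linear intensity was therefore taken from the deposited intensity table at the positions the normalized table lists, with 0 mismatches between the tables on every array. The group rule removed 36056 values and 7849 probes. A probe is called listed on an array where the normalized table holds a value.

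A gene family is a gene name of the deposited annotation. Its value is the log2 of the share of an array's total intensity carried by its listed probes, with unlisted probes at 0. Of 1075 families 561 had a mean of at least 5 listed probes and were tested. Probe values are log2 intensity minus the median of the array over the 40140 probes listed on all 15 arrays, tested where listed on at least 2 of 3 arrays in each group compared.

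Families, probes and category shares were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off), with 1 pooled spread over the 5 groups, no block, and Benjamini-Hochberg adjustment at 0.05 within each comparison. The comparisons were each treatment against CC, MM against MC, HH against HC, HC against MC, HH against MM, the mean of the 4 treatments against CC, the mean biochar difference within slurry rate, and the difference of the biochar differences. Errors beside log2 changes are standard errors. Values beside group means are SD.

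Named families are the 10 largest rises and 10 largest falls past the test without overlap between the groups, or the 5 lowest p where fewer than 5 passed. Of these, the text on single treatments gives the 3 largest on each side. Named probes are the 3 largest on each side by the same rule. A further 24 families of well known steps were chosen before the values were seen.

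The 26 gene lists were fixed before any value was seen, and 22 had at least 3 families and were tested with camera at a preset correlation of 0.01. An estimated correlation and fry were the alternatives. Enrichment of categories among the families past the test used the Fisher exact test against all 561 families, with Benjamini-Hochberg adjustment.

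Listed probes, the Shannon index (natural log) and the share of the brightest 1% of probes were tested by exact permutation of the difference of means, with 455 splits for treated against control, 400 for biochar within slurry rate, and 100000 permutations for the F statistic over 5 groups. Dissimilarity was Bray-Curtis on shares of intensity in vegan 2.7.1, with exact permutation for pairs of groups and 9999 permutations for the spread. Tables were read with the data.table package (version 1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

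Category, domain and phylum shares are shares of total intensity, for groups with a mean of at least 50 listed probes. Domain and phylum were read from the deposited lineage. Category names that differ only in the case of the first letter were merged for shares.

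The alternatives tried were the replicate number as a block, leaving out each array in turn, no scaling to the array total, probes listed on all 15 arrays, the mean log2 over listed probes, other minimum numbers of listed probes, the intensity table without the group rule, the compared groups fitted alone, eBayes with trend and robust, quantile normalization, other filters and centring of probes, other weights, dissimilarities and shares, and other list tests. Added once the values had been seen were the sum of deposited scores per family (not scaled to the array total), the deposited score per probe, and a block of 4 sets of consecutive arrays over the 12 arrays of CC, MC, MM and HC. Also added were leaving out MC replicate 1 with MM replicate 3, and methanogenesis without a family that the annotation places under mercury.

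The steps were tested on simulated data of the same shape with 200 changed families of 561. Noise was drawn independently for each family or probe, without an effect shared within an array, so real data may give lower shares found. With fewer changed families the adjustment would be stricter, which could also lower these shares. For treated against control 73.1%, 94.0% and 98.5% of changes of 0.25, 0.5 and 1 log2 were found, and 9 of 361 unchanged families were called. For HH against CC the shares found were 53.7%, 82.1% and 95.5%. For the mean biochar effect they were 58.2%, 92.5% and 98.5%, with 7 of 361 unchanged families called. For HH against HC 44.8%, 88.1% and 98.5% were found, and for the difference of biochar differences 60% and 94% of changes of 0.5 and 1 log2. Of changed probes 13.4%, 55.2% and 90.9% were found at 1, 2 and 3 log2 in HH against CC, with 7 of 47077 unchanged probes called, and 17.9%, 79.1% and 93.9% for treated against control, with 7 of 46733 called.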

Results

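Soil DNA from a poplar plantation in Jiangsu Province was labelled with Cy3 and hybridized to 15 functional gene arrays, 3 for each of 5 groups. The control group (CC) received nothing. The plots of MC received biogas slurry at 250 m3 per ha and those of HC at 375 m3 per ha. The plots of MM received 250 m3 of slurry with 80 t of biochar per ha, and those of HH received 375 m3 with 120 t, all for 5 years. Per the labels each group comes from triplicate field plots, so n is 3 plots per group throughout.

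Each array listed between 44879 and 71413 probes after probes seen on only 1 of the 3 arrays of a group had been removed. The summed intensity of an array lay between 1.41e+08 and 1.48e+08, and the median listed value was 1277 on CC replicate 1 and 805 on HH replicate 3. An exact test of 3 arrays against 3 cannot give p below 0.1.

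Arrays of treated plots listed more functional gene probes than those of control plots. Control arrays listed 45933 ± 1046 probes (mean ± SD), MC 54868 ± 6859, MM 60447 ± 1880, HC 65826 ± 1136 and HH 69231 ± 2452. HH arrays shared 17129 probes that no control array listed, while control arrays shared 27 that no HH array listed. The same counts were 14904 and 87 for HC, 9067 and 26 for MM, and 1687 and 46 for MC. All these counts follow the group rule, which also removed values of probes seen on only 1 control array. Before the rule removed values, 13279 probes on all HH arrays were on no control array. MC replicate 1 listed 46948 probes, inside the control range of 44879 to 46970, while MC replicates 2 and 3 listed 58751 and 58904. The 5 groups differed (permutation F = 21.7, p = 2e-05), and treated arrays listed 16660 more probes than control arrays (exact p = 0.0044, n = 12 and 3). Arrays of plots with biochar listed 4492 more probes within slurry rate (exact p = 0.03, n = 6 and 6), but the call ended in the intensity table without the group rule (4962, exact p = 0.135), without the dimmest 25% of values (1782, exact p = 0.15) and without MC replicate 1 and MM replicate 3 together (2032, exact p = 0.1). Without MC replicate 1 alone the biochar difference was 2512 (exact p = 0.05), and without single arrays p reached 0.11 (exact).

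**Figure D1:**
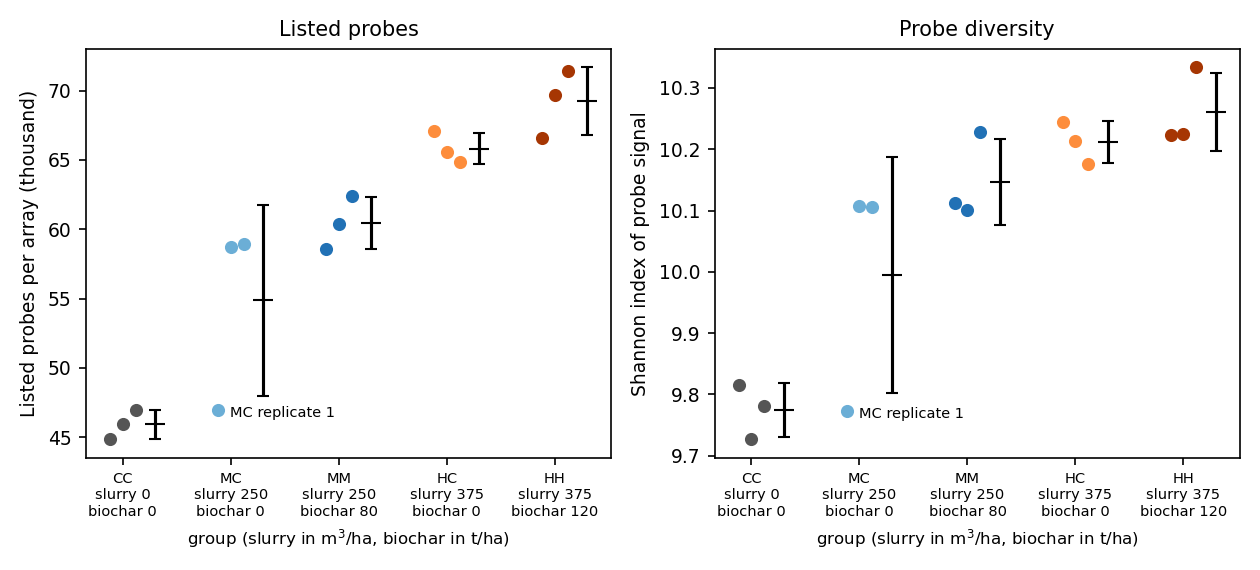
Listed probes and Shannon index of each array, with the mean and SD of each group (n = 3). MC replicate 1 lies at the control level in both panels.

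Probe diversity was higher, and the signal spread over more probes, on arrays of treated plots. Since the index rises with the number of listed probes, the explanations weighed below for that number stay open here too. They include sets of consecutive arrays and dim probes below detection on control arrays. The Shannon index (natural log) was 9.77 ± 0.0443 in CC, 9.995 ± 0.193 in MC, 10.1 ± 0.0700 in MM, 10.2 ± 0.0343 in HC and 10.3 ± 0.0635 in HH. Treated arrays exceeded control arrays by 0.379 (exact p = 0.00659, n = 12 and 3), and the biochar difference of 0.1004 did not pass (exact p = 0.105, n = 6 and 6). With log2 values as weights the biochar difference was 0.0756 and passed (exact p = 0.03). Such weights are nearly even over probes, so this index mostly restates the number of listed probes, whose biochar call ended without the group rule. The brightest 1% of probes carried 19.9% of the signal in CC and 17.4% in HH, and their share was 2.09 points lower on treated arrays (exact p = 0.011).

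Group explained 49.6% of the Bray-Curtis dissimilarity between arrays (permutation p = 0.00247). No difference in spread between groups was detected (permutation p = 0.91), but with 3 arrays per group this test is weak. The mean dissimilarity within a group ran from 0.140 in MM to 0.222 in HH. Against control arrays, group explained 59.5% for HC, 54.8% for MM, 50.5% for HH and 45.1% for MC, each at exact p = 0.1, the lowest value this test can give. Within slurry rate, biochar explained 8.56% (exact p = 0.405), which became 13.9% with Jaccard dissimilarity on listed probes (exact p = 0.005). The group rule makes the listed probes of a group's arrays more alike, and the permutations did not repeat that rule. This Jaccard result was therefore partly fixed in advance and decides nothing on biochar. On the first principal axis, with 45.5% of the variance of the gene family shares, control arrays lay between -6.49 and -4.43 and MC replicate 1 lay at -5.11. All other treated arrays had positive scores on that axis. On the second axis MC replicate 1 had the highest score of all arrays (4.62), outside the control range of -3.36 to 0.968.

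**Figure D2:**
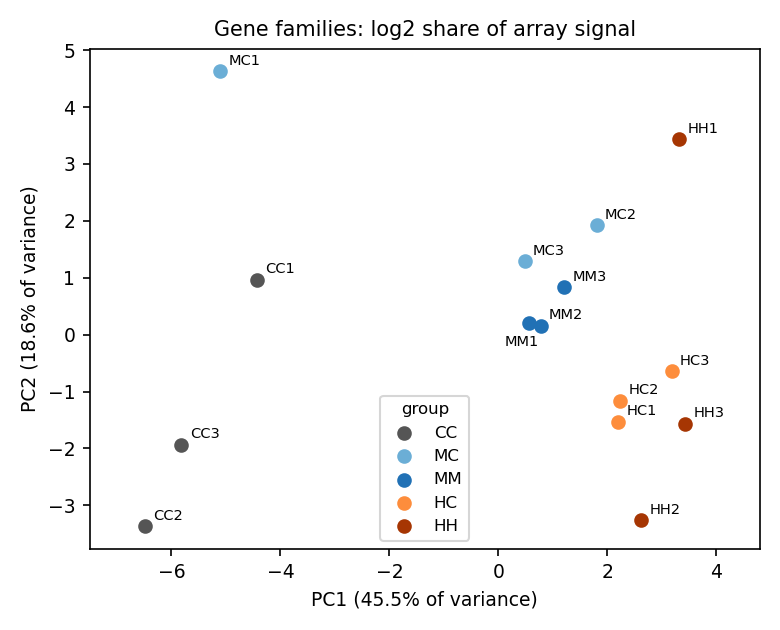
Principal components of log2 gene family shares for all 15 arrays. The axes hold 45.5% and 18.6% of the variance.

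Over the 4 treatments combined, 178 of 561 gene families gained share of the signal and 35 lost it against control soil (limma with Benjamini-Hochberg adjustment at 0.05, n = 12 and 3). The median over all families was 0.09 log2, -0.52 with the mean over listed probes and 0.47 with the sum of deposited scores, so directions are those of shares of the signal and are also given relative to these medians. That sum is not scaled to the array total and rises with the number of listed probes. As treated arrays listed more probes, its turn to positive values was largely fixed in advance. The mean over listed probes falls where dim probes are added. Probes on all HH arrays and on no CC array were mostly dim (median brightness percentile 17.8 on HH arrays). The turn of that mean to negative values was therefore also largely fixed in advance. Of the families that rose 13 stayed above 0 with the mean over listed probes and 116 stayed above its median. Of those that fell 0 stayed below 0 with the sum of scores and 23 stayed below its median. On probes listed on all 15 arrays 44 families rose and 23 fell, where of 187 called families with a value there 153 kept their sign and 38 passed again, and without CC replicate 2 the count past the test was 116.

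Among single families that gained share, 5f1_ppn, which degrades polyphosphate, rose by 1.35 ± 0.13 log2 (limma adjusted p = 8.08e-05) but turned to -1.08 with the mean over listed probes, 0.57 below the median. The acid shock gene asr rose by 1.21 ± 0.23 (limma adjusted p = 0.00219) and kept its sign under every scaling that gave it a value. The sodium/proton antiporter nhaC (0.97 ± 0.13), sucD, placed under carbon fixation in the annotation (0.92 ± 0.13), and the protist markers GAPDH_Parabasalia (1.02 ± 0.13) and actin_Stramenopiles (0.87 ± 0.13) turned negative with that mean but stayed above its median, by 0.14, 0.35, 0.13 and 0.11. The sortase gene srt (0.86 ± 0.14), hfq, an RNA chaperone gene (0.74 ± 0.18), and the polymerase family RdRp_partitiviridae of fungal viruses (0.72 ± 0.11) turned negative and lay below that median by 0.14, 0.04 and 0.13. Added dim probes on treated arrays largely fixed these negative turns in advance. Without CC replicate 3 hfq did not pass (limma adjusted p = 0.0582). The family calcineurin_A_fungi (0.75 ± 0.13) kept its sign but lay at the median with the sum of deposited scores (-0.00).

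Among single families that lost share, with the sum of deposited scores all turned positive, while hao, which oxidizes hydroxylamine in nitrification (-0.53 ± 0.08 log2), sqr of sulfide oxidation (-0.54 ± 0.10) and nira of nitrate assimilation (-0.37 ± 0.06) stayed below its median by 0.16, 0.08 and 0.17. More listed probes on treated arrays largely fixed this turn in advance, unlike the place relative to that median. The families nitrite_transporter (-0.81 ± 0.22), por_DiC4HB of carbon fixation (-0.66 ± 0.08), gdh, a glutamate dehydrogenase gene (-0.60 ± 0.08), fmdB_fwdB of methanogenesis (-0.60 ± 0.13), the reductase gene dmsa (-0.51 ± 0.08) and the cold shock gene cspA (-0.40 ± 0.07) lay above that median, by 0.05, 0.02, 0.01, 0.19, 0.11 and 0.10. With the mean over listed probes nira stayed negative but lay 0.21 above the median. On probes listed on all 15 arrays gdh (0.08), dmsa (0.03) and nira (0.01) did not keep their fall, whereas hao (-0.40) and por_DiC4HB (-0.49) did. In gdh a single probe held 54.3% of the family signal, and nitrite_transporter lost its call in 2 of 15 fits with an array left out (highest limma adjusted p = 0.0649).

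Among 24 families for well known steps of the carbon, nitrogen, sulfur and phosphorus cycles and metal resistance, 5 rose, 0 fell and 19 did not pass. With the mean over listed probes nosz and dsra lay above the median of all families by 0.04 and 0.01. Below it lay pmoa, nrfa and phenol_oxidase, by 0.15, 0.05 and 0.08. All 5 were negative with that mean, a turn that added dim probes largely fixed in advance. They were pmoa of methane oxidation (0.29 ± 0.04), nrfa of nitrite reduction to ammonium (0.34 ± 0.06), nosz of nitrous oxide reduction (0.19 ± 0.04), dsra of sulfite reduction (0.16 ± 0.04) and phenol_oxidase (0.13 ± 0.04). The last lost its call in 3 of 15 fits with an array left out (highest limma adjusted p = 0.0943) and was at -0.03 on probes listed on all 15 arrays. The families amoa (-0.04 ± 0.08, limma adjusted p = 0.703), nirs (-0.00 ± 0.06, limma adjusted p = 0.979), narg (-0.00 ± 0.04, limma adjusted p = 0.959) and nifh (0.08 ± 0.05, limma adjusted p = 0.238) did not pass.

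**Figure D3:**
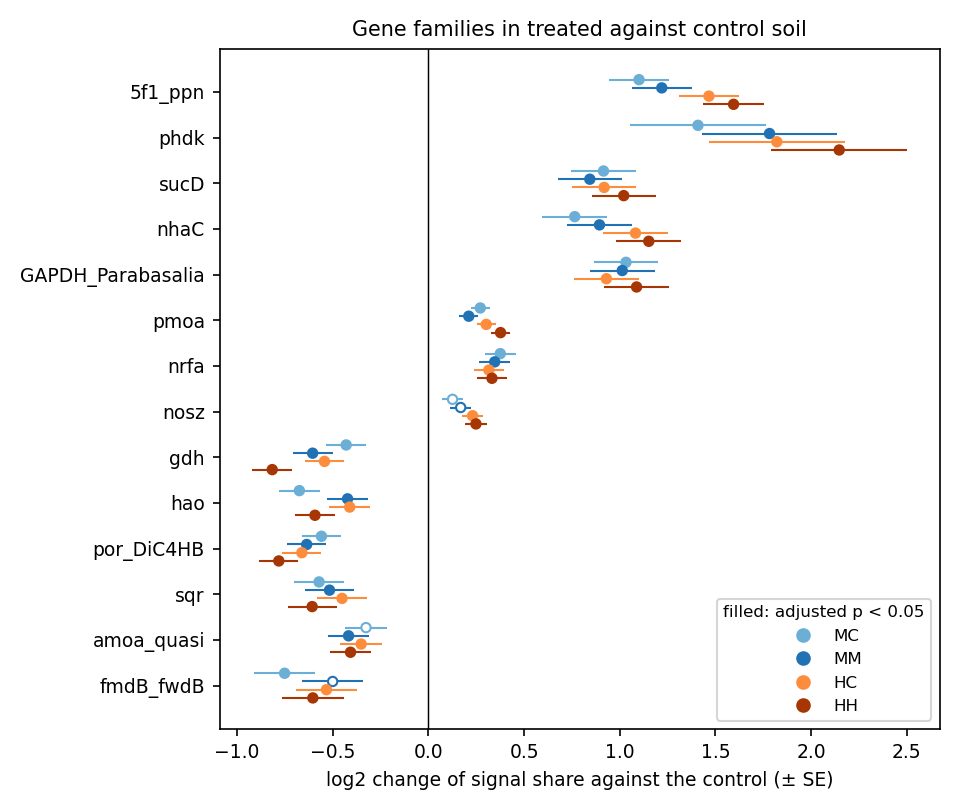
Change in share of the signal against control, in log2 with its standard error, for 14 families in each treatment. Of the families that rose, only phdk stayed positive in all 4 treatments with the mean over listed probes, which falls where dim probes are added. Those that fell turned positive with the sum of deposited scores, which rises with the number of listed probes.

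Of 22 fixed gene lists, nitrification was the only one to pass in treated against control soil. Of its 3 members 0 rose, hao and amoa_quasi (-0.38 ± 0.09) fell by share, turning positive with the sum of deposited scores, and amoa did not pass. The camera adjusted p was 0.043 at a preset correlation in limma, and adjusted p = 0.791 with an estimated correlation. The list did not pass on probes listed on all 15 arrays or when CC replicate 3, MC replicate 1, HC replicate 2 or HH replicate 2 or 3 was left out. Of 7 denitrification families 1 rose, nosz, 0 fell and 6 did not pass, among them nirk (0.07 ± 0.05) and norb (-0.24 ± 0.12). Of 8 families for sulfate and sulfite reduction 4 gained share, dsra, aps_apra (0.29 ± 0.09), AprA (0.57 ± 0.13) and Sir (0.25 ± 0.08), all turning negative with the mean over listed probes, and 0 fell. Of 10 families for lignin and aromatic compounds 5 gained share, among them limeh (0.49 ± 0.10) and vdh (0.36 ± 0.08), which turned negative with that mean, and 0 fell. Matched by name, these 10 include lip, which the annotation places under virulence, and camdcab, which it places under terpenoids. None of the 5 families in the list for phosphorus cycling, which leaves out 5f1_ppn, and none of the 3 of chitin degradation passed.

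In soil with slurry at the lower rate (MC) 52 families differed from control, 38 up and 14 down in share of the signal. Among families without overlap between the groups the largest rises were asr (1.29 ± 0.29 log2), 5f1_ppn (1.10 ± 0.16) and GAPDH_Parabasalia (1.03 ± 0.17), the last 2 turning negative with the mean over listed probes. The largest falls were fmdB_fwdB (-0.75 ± 0.16), hao (-0.67 ± 0.11) and sqr (-0.57 ± 0.13), all turning positive with the sum of deposited scores. Of these, asr, fmdB_fwdB and sqr each lost their call in 4 of 15 fits with an array left out (highest limma adjusted p = 0.0956, 0.0781 and 0.0959). Of the rises 27 stayed above the median of all families with that mean, and of the falls 9 stayed below it with that sum. The changes passed limma at a Benjamini-Hochberg adjusted p of 0.05 (n = 3 and 3), and over all 561 families the groups did not overlap in 161 (28.7%), where 10% would by chance. The count was 7 without MC replicate 2, 126 without MC replicate 1, 0 with the arrays of both groups fitted alone, and 21 with 4 sets of consecutive arrays as a block.

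With slurry at the lower rate and biochar (MM) 74 families differed from control, 62 up and 12 down. The family phdk, which acts on polycyclic aromatic compounds, rose by 1.78 ± 0.35 log2 and asr by 1.14 ± 0.29, while 5f1_ppn rose by 1.22 ± 0.16 but turned to -0.96 with the mean over listed probes. The falls of por_DiC4HB (-0.64 ± 0.10), gdh (-0.61 ± 0.10) and the carotenoid family phytoene_synthase_protist (-0.59 ± 0.13) turned positive with the sum of deposited scores, and gdh also on probes listed on all 15 arrays (0.10). With an array left out, asr lost its call in 5 of 15 fits (highest limma adjusted p = 0.104) and phytoene_synthase_protist in 3 (0.0672). The nitrification list passed, with hao (-0.42 ± 0.11) and amoa_quasi (-0.42 ± 0.11) lower by share though higher with the sum of scores (camera in limma, adjusted p = 0.013, and adjusted p = 0.542 with an estimated correlation). The list did not pass on probes listed on all 15 arrays, where hao was at -0.29, amoa_quasi at -0.26 and amoa at 0.08. Of the rises 37 stayed above the median with that mean and of the falls 6 below it with that sum. Over all families the groups did not overlap in 249 (44.4%), where 10% would by chance. The count was 18 without MM replicate 2, 141 without MC replicate 1, 0 on probes listed on all 15 arrays, and 1 with the array sets as a block (limma, n = 3 and 3).

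In soil with slurry at the higher rate (HC) 177 families differed from control, 150 up and 27 down. The largest rises were phdk (1.82 ± 0.35 log2), 5f1_ppn (1.47 ± 0.16) and the calcium exchanger family Ca_vacuolar_exchanger (1.28 ± 0.29), the last 2 turning negative with the mean over listed probes. The largest falls were nitrite_transporter (-0.80 ± 0.28, limma adjusted p = 0.0481), por_DiC4HB (-0.66 ± 0.10) and phytoene_synthase_protist (-0.59 ± 0.13), all turning positive with the sum of deposited scores. The fall of nitrite_transporter lost its call in 11 of 15 fits with an array left out (highest limma adjusted p = 0.189) and in 6 of 10 other alternatives, and it was reversed in 1. Besides pmoa (0.30 ± 0.05) and nrfa (0.32 ± 0.08), HC carried more nosz (0.23 ± 0.06) and nirk (0.18 ± 0.06) by share, and all 4 turned negative with the mean over listed probes. Of the rises 92 stayed above the median with that mean and of the falls 19 below it with that sum. Over all families the groups did not overlap in 281 (50.1%), where 10% would by chance (limma, n = 3 and 3). The count was 0 with the array sets as a block, 13 on probes listed on all 15 arrays and 93 without HC replicate 3.

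With slurry at the higher rate and biochar (HH) 189 families differed from control, 160 up and 29 down. The family phdk rose by 2.15 ± 0.35 log2 and asr by 1.37 ± 0.29, and 5f1_ppn rose by 1.59 ± 0.16 but turned to -1.36 with the mean over listed probes. The falls of nitrite_transporter (-0.93 ± 0.28), gdh (-0.82 ± 0.10) and por_DiC4HB (-0.78 ± 0.10) turned positive with the sum of deposited scores, and gdh was at 0.00 on probes listed on all 15 arrays. The fall of nitrite_transporter lost its call in 3 of 15 fits with an array left out (highest limma adjusted p = 0.0733). Of 20 virus families 12 gained share, more than the 160 of 561 families overall would give (Fisher exact test, Benjamini-Hochberg adjusted p = 0.0439). Over the treatments combined 11 of the 20 gained share, which did not pass (Fisher exact test, Benjamini-Hochberg adjusted p = 0.174). In HH the subcategory of eukaryotic viruses, with 10 of 16 families higher, did not pass (Fisher exact test, Benjamini-Hochberg adjusted p = 0.108). This test treats families as independent, although they were measured on the same arrays. Of the rises 96 stayed above the median with that mean and of the falls 19 below it with that sum. Over all families the groups did not overlap in 279 (49.7%), where 10% would by chance (limma, n = 3 and 3). The count was 8 on probes listed on all 15 arrays, and the array sets could not be blocked because the last set held HH arrays alone.

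Between the slurry rates few families could be told apart. Without biochar, the siderophore gene sidA was 1.03 ± 0.16 log2 higher in HC than in MC (limma adjusted p = 0.0139), and 0 other families passed, with 107 at unadjusted p under 0.05. It did not pass on probes listed on all 15 arrays (0.50), with the mean over listed probes (0.08), with the 2 groups fitted alone, with the array sets as a block (0.66), or without HC replicate 2 or HC replicate 3 (highest limma adjusted p = 0.108). With biochar, HH against MM gave 0 families by limma with Benjamini-Hochberg adjustment and 28 at unadjusted p under 0.05. With the mean over listed probes 344 families passed for HC against MC and 69 for HH against MM, nearly all lower, and with the sum of deposited scores 468 and 117 passed, all higher. For HC against MC more families than in the first analysis also passed with the replicate number as a block and with quantile normalization, as given below.

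No single gene family differed detectably between soil with and without biochar. By limma with Benjamini-Hochberg adjustment 0 of 561 families passed for MM against MC (9 at unadjusted p under 0.05), 0 for HH against HC (18) and 0 for the mean over both rates (26). With the sum of deposited scores 7, 0 and 10 passed, all higher, and with the mean over listed probes 1, 5 and 2, all lower. For phdk the mean biochar difference was 0.35 ± 0.25 log2 (limma adjusted p = 0.984), for 24 families of well known steps 0 passed, and of the 22 gene lists 0 passed. The biochar difference at the higher rate did not differ from that at the lower rate in any family (limma, 0 passed, 8 at unadjusted p under 0.05), though 1 passed with either of these scalings. At the higher slurry rate the biochar dose was also higher, so this comparison mixes both doses. On simulated data of the same design, 92.5% of changes of 0.5 log2 were found for the mean biochar effect and 58.2% of changes of 0.25 log2.

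In the gene categories of the annotation, antibiotic resistance lost share while virus, protist and phosphorus genes gained it. Antibiotic resistance held 18.1% of the signal in CC and 16.9% in HH (treated against control -0.07 ± 0.01 log2, limma adjusted p = 0.000161), a fall that disappeared on probes listed on all 15 arrays (0.00). Virus genes rose by 0.20 ± 0.02 log2, from 0.428% to 0.513% in HH, and protist genes by 0.26 ± 0.06, the latter also on probes listed on all 15 arrays (0.15, limma adjusted p = 0.0165). Phosphorus (0.06 ± 0.01), electron transfer (0.08 ± 0.01) and carbon cycling (0.03 ± 0.01) rose, and pigments (-0.11 ± 0.03) fell, without a change of sign under the other scalings. Nitrogen genes fell by 0.06 ± 0.02 but rose as a share of the number of listed probes (0.02), and organic contaminant degradation rose by 0.04 ± 0.01 but fell by that measure (-0.04). In total 8 of 17 categories rose and 3 fell (limma, n = 12 and 3), against 2 past the test on probes listed on all 15 arrays.

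With biochar 1 category, electron transfer, was higher by 0.08 ± 0.01 log2 (limma adjusted p = 0.0017, n = 6 and 6), and 0 passed on probes listed on all 15 arrays or as a share of the number of listed probes. Between HH and MM, electron transfer (0.08 ± 0.02), virus (0.10 ± 0.03) and carbon cycling (0.03 ± 0.01) were higher and antibiotic resistance was lower (-0.05 ± 0.01) by limma, with 0 past the test on probes listed on all 15 arrays. Between HC and MC 0 categories passed limma, with 3 at unadjusted p under 0.05.

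**Figure D4:**
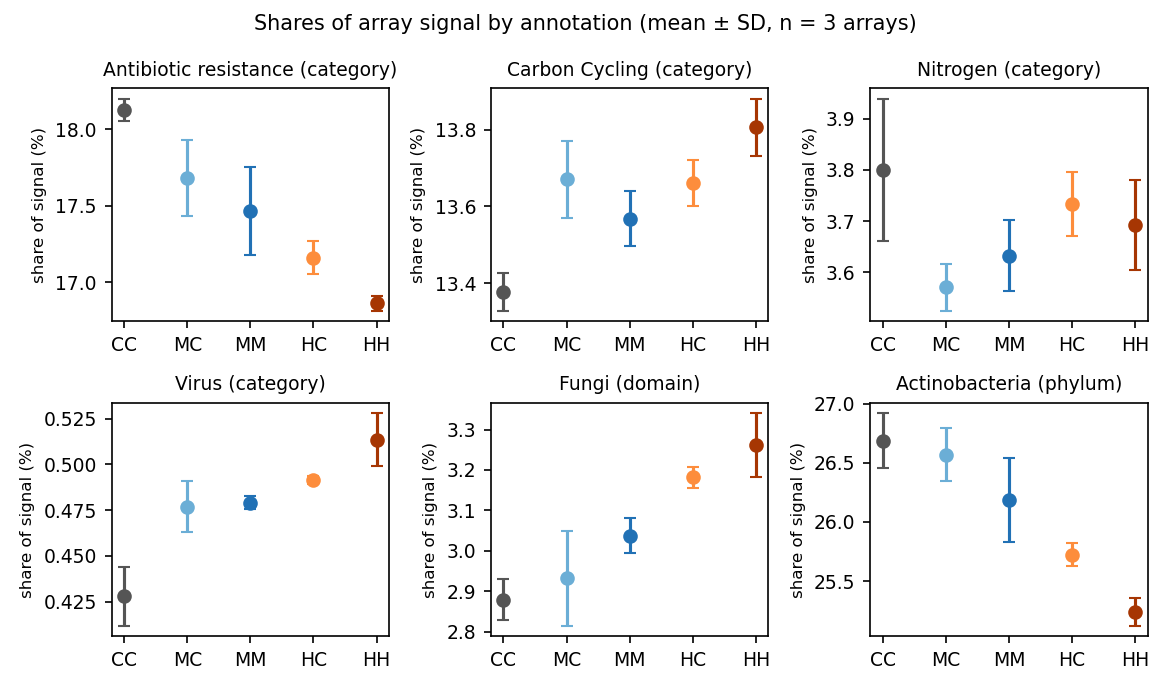
Share of the signal of 6 gene categories and lineages, as the mean and SD over the arrays of each group (n = 3). The vertical axes do not start at 0.

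The annotation assigns each single probe to a gene variant of an organism, in some cases only an uncultured bacterium. Whether a probe binds that variant alone was not tested. In treated against control soil a pstC variant of Synechococcus sp. JA-2-3B_a(2-13), a phosphate transporter gene, rose by 2.50 ± 0.34 log2 and a ferroxidase variant of Magnaporthe grisea by 2.36 ± 0.25. A nirs variant of an uncultured bacterium fell by 3.07 ± 0.20 and a hao variant of an uncultured bacterium by 2.50 ± 0.38. In HH a kefBC variant of Pseudomonas sp. S9, a potassium efflux gene, rose by 3.40 ± 0.33. None of these changed sign under the other scalings, but changes this large could hardly have turned. The median of all probes in treated soil was -0.12 log2 in the first analysis and 0.44 with quantile normalization. By limma with Benjamini-Hochberg adjustment 8033 probes rose and 5085 fell in treated against control soil, and 5369 and 973 in MC, 3592 and 1164 in MM, 2127 and 1413 in HC, and 5236 and 4145 in HH (n = 3 and 3). With quantile normalization nearly all rose, 17517 up and 222 down in HH, and with the array sets as a block 2 probes passed in MC, 1 in MM and 0 in HC. Without CC replicate 3 the count was 124 for treated against control soil, 0 for MC, 2 for HC and 94 for HH, and without MM replicate 2 it was 0 for MM. No probe passed limma for biochar (2095 at unadjusted p under 0.05) or between the slurry rates without biochar (4154 for HC against MC). None passed for HH against MM (2474), which differ in both slurry and biochar dose.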

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

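Values that the normalized table leaves out were unevenly spread over the arrays. The number of values on probes listed on only 1 of the 3 arrays of a group was 4462 for MC replicate 2, 7154 for MM replicate 3 and 4007 for HH replicate 3, each above the highest control array (3840, CC replicate 3). The mean was 2565 ± 1886 on treated and 1760 ± 1801 on control arrays (exact p = 0.523).

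The rise in listed probes, with MC replicate 1 at the control level, was weighed first, and the tests of array sets and of slurry were chosen after the values had been seen, that of dim probes before. In table order, 4 sets of 4, 4, 4 and 3 consecutive arrays explained 96.0% of the variance in listed values per array and the 5 groups 81.0%. Runs of 2, 5, 6 and 7 arrays explained 98.7%, 73.3%, 68.4% and 69.9%, and as runs of 4 were chosen from these values and no scan order is given, a set effect stays open. Of 12 treated arrays 1 lay in the control range, which could not tell slurry from sets, because sets and treatments run almost in parallel. Probes on all HH arrays and on no CC array, even before the group rule removed values, had a median brightness percentile of 17.8 on HH arrays over 13279 probes. This met the prediction for dim probes that fell below detection on control arrays. Rarer gene variants that gained in treated soil would also be dim, so the test cannot tell these apart.

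For families higher in treated soil, the test of added probes was chosen after the values had been seen and that of array sets before. On probes listed on all 15 arrays the median change of 154 families that rose was 0.375 of its value in the first analysis. Since these probes exclude any missing on control arrays, a smaller rise was partly fixed in advance, and whether added probes caused the rise stays open. With the array sets as a block the median HC change of 150 families was 0.354 of its value (0.15 log2 with a median SE of 0.19, against 0.43), and since the block ties CC to HC through MC replicate 1 and MM replicate 3 alone, a set effect stays open. Neither test excludes biology, since rarer gene variants in treated soil could also add listed probes.

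For families lower in treated soil both tests were chosen before the values had been seen. Without the brightest probe of each family the median change of 35 families was 0.473 of its value, so single bright probes may carry about as much of the fall as all others. Over 347 of the 348 families that did not pass, those whose brightest probe had a value, that brightest probe changed its share by a median of -0.37 log2, so a lower share of bright probes on treated arrays could explain part of the fall. These tests cannot separate saturation or competition on the array from a real fall of abundant variants.

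Regrouping the arrays tested whether counts of calls as large could come from chance, and these tests were chosen before the values had been seen. For treated against control there were 213 families against at most 12 in other splits (the real split was the only 1 of 100 to reach it). The probes were 13118 against at most 475. The grouping as a whole was thus unlike an arbitrary one. The other splits mixed all 5 groups, so differences between groups entered their spread and could lower their counts. Array sets and treatments run almost in parallel, so these counts cannot tell treatment from sets. For biochar chance could not be excluded, and with 0 calls this was fixed in advance, since every split (100 of 100) reaches that count, with 0 families against at most 2, 0 probes against at most 286, and 0 against at most 9 families for the difference between rates. For pairs of groups there were too few splits (10): the families were 52 against at most 21 in MC, 177 against 1 in HC, 74 against 1 in MM, 189 against 1 in HH, 1 against 0 in HC against MC, 0 against 0 in MM against MC and in HH against MM, and 0 against 2 in HH against HC. The probes were 6342 against at most 5796 in MC, 3540 against 2 in HC, 4756 against 0 in MM, 9381 against 0 in HH, 0 against 463 in HH against HC, and 0 against 0 in the other 3 pairs. In MC the highest other split grouped CC replicate 1 with MC replicates 2 and 3.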

How the results depend on the processing

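Named families kept their sign in 52 of 52 values with the replicate block, with eBayes trend and robust, with quantile normalization, without a minimum of listed probes, with the compared groups fitted alone and in the intensity table without the group rule, and in 19 of 19 with the array sets as a block, where only 2 still passed limma. Treated against control kept its side of the threshold for listed probes (15858 to 18082, highest exact p = 0.022) and the Shannon index (0.355 to 0.414, highest exact p = 0.033) with each array left out. The cause of each change below was not tested, except that a stricter filter tests fewer families or probes and that leaving out an array leaves fewer arrays. Background correction by normexp was not run, as no background column is given, and neither was a slide block, as no slide is given. HH and treated against control could not be fitted with the array sets as a block, because the last set holds HH arrays alone.

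Replicate numbers gave no sign of shared plots. Residuals of arrays with the same number correlated at a mean r of 0.0253 (lowest -0.253), those with different numbers at -0.0101, and 7 of 15 arrays correlated best with an array of their own number. With the number as a block families past the test were 45 in MC, 175 in HC, 80 in MM, 198 in HH and 225 in treated soil, but 12 for HC against MC. Probes past the test were then 152 in MC (124 up, 28 down), 9 in HC, 6 in MM and 7508 in HH (4200 up, 3308 down).

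Without scaling to the array total 83 families passed in MC and 144 in MM (133 up, 11 down), and amoa was at 0.00 (0.00408). On probes listed on all 15 arrays 12 families passed in MC, 13 in HC, 0 in MM, 8 in HH, 67 in treated soil and 0 for HC against MC. The family gdh was then at 0.0812 in treated soil, 0.10 in MM and 0.00 (0.00103) in HH, dmsa at 0.0314, nira at 0.0123, amoa at 0.18 and phenol_oxidase at -0.0294. For probes the HC count was 1928. For shares it was 2 categories, 1 domain and 2 phyla in treated soil, 0 of each for HH against MM, 0 domains and 0 phyla for HC against MC, and 0 categories for biochar. The list count was 0 in MM and 0 in treated soil.

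With the mean log2 over listed probes the families past the test were 180 in MC (4 up, 176 down), 503 in HC (4 up, 499 down), 454 in MM (2 up, 452 down), 527 in HH (2 up, 525 down), 506 in treated soil (4 up, 502 down), 344 for HC against MC (1 up, 343 down), 69 for HH against MM, 5 for HH against HC, 1 for MM against MC, 2 for biochar and 1 for the difference between rates. The values that turned in treated soil were 5f1_ppn -1.08, GAPDH_Parabasalia -0.39, nhaC -0.37, sucD -0.17, actin_Stramenopiles -0.41, srt -0.66, hfq -0.55, RdRp_partitiviridae -0.64, pmoa -0.67, nrfa -0.56, nosz -0.47, dsra -0.51 and phenol_oxidase -0.60. The family 5f1_ppn was at -0.92 in MC, -1.09 in HC, -0.96 in MM and -1.36 in HH, GAPDH_Parabasalia at -0.21 in MC and Ca_vacuolar_exchanger at -0.23 in HC.

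With the sum of deposited scores 444 families passed in MC, 547 in HC, 536 in MM, 555 in HH, 554 in treated soil, 7 for MM against MC, 468 for HC against MC, 117 for HH against MM and 10 for biochar, all up, and 1 lower for the difference between rates. The values that turned in treated soil were nitrite_transporter 0.52, por_DiC4HB 0.50, gdh 0.48, fmdB_fwdB 0.66, sqr 0.39, hao 0.31, dmsa 0.58, cspA 0.58, nira 0.30, Host_recognition_T4_type 0.85, amoa 0.48 and amoa_quasi 0.67. In MC they were fmdB_fwdB 0.25, hao 0.13 and sqr 0.20, in HC nitrite_transporter 0.58, por_DiC4HB 0.59 and phytoene_synthase_protist 0.15, in MM por_DiC4HB 0.45, gdh 0.47 and phytoene_synthase_protist 0.14, and in HH nitrite_transporter 0.75, gdh 0.66 and por_DiC4HB 0.61. The deposited score per probe gave 11126 probes in MC (10986 up, 140 down), 15573 in HC (15411 up, 162 down), 10856 in MM (10774 up, 82 down), 18038 in HH (17878 up, 160 down) and 8 for HH against MM.

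A minimum of 20 listed probes gave 117 families in HC, 138 in treated soil and 0 for HC against MC, and no minimum gave 81 in MC and 114 in MM. Quantile normalization gave 42 families in MM and 3 for HC against MC, and 11650 probes in MC (11407 up, 243 down), 16080 in HC (15852 up, 228 down), 11193 in MM (11057 up, 136 down), 17739 in HH (17517 up, 222 down) and 9 for HH against MM. The median change of all probes in treated soil was 0.44 log2 with quantile normalization and -0.12 without it. With the compared groups fitted alone 0 families passed in MC and 0 for HC against MC. The array sets as a block gave 21 families in MC (12 up, 9 down), 0 in HC, 1 in MM and 0 for HC against MC, and 2 probes in MC, 0 in HC and 1 in MM.

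Without a probe filter 21 probes passed in MC (9 up, 12 down), 11 in MM (2 up, 9 down), 77 for HH against HC (4 up, 73 down), 3 for HC against MC, 1 for HH against MM and 1 for biochar. Values not centred gave 5666 probes in HC (4839 up, 827 down) and 3 for HH against MM. Without the dimmest 25% of probes 2006 passed in HC and 3005 in MM, and the intensity table without the group rule gave 2 for HH against MM. The biochar difference in listed probes was 4962 in that table (exact p = 0.135), 1782 for probes above the lowest 25% of values (exact p = 0.15) and 2032 with both MC replicate 1 and MM replicate 3 left out (exact p = 0.1). For biochar the Shannon index with log2 weights, which mostly restates the number of listed probes, gave 0.0756 (exact p = 0.03). Jaccard dissimilarity gave 13.9% (exact p = 0.005), partly fixed in advance by the group rule, which the permutations did not repeat.

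As a share of the number of listed probes 13 categories, 6 domains and 13 phyla passed for HC against MC, 8 categories and 4 domains for HH against MM, 17 phyla in treated soil and 0 categories for biochar. With an estimated correlation 0 lists passed in MM and 0 in treated soil, and with fry 3 in MC, 10 in HC, 4 in MM, 14 in HH and 14 in treated soil (12 up, 2 down).

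With each array left out the families past the test were 7 (without MC replicate 2) to 126 (without MC replicate 1) in MC, 93 (without HC replicate 3) to 219 in HC, 18 (without MM replicate 2) to 141 (without MC replicate 1) in MM, 116 (without CC replicate 2) to 261 in treated soil, 0 to 5 for HC against MC and 0 to 1 for HH against MM. Family counts moved by over 1.5 times without any CC array or any MC array in MC, without CC replicates 2 and 3 and HC replicates 2 and 3 in HC, without CC replicates 2 and 3, MC replicate 1 and any MM array in MM, and without CC replicates 2 and 3 in treated soil. For HC against MC they so moved without any HC array or HH replicates 1 and 2, and for HH against MM without HC replicate 3. The family amoa ranged from -0.10 to 0.0252 (without CC replicate 3).

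Probe counts ranged from 0 (without CC replicate 3) to 11071 (without CC replicate 1) in MC, 2 (without CC replicate 2) to 8637 (without CC replicate 1) in HC, 0 (without MM replicate 2) to 9229 (without CC replicate 1) in MM, 94 (without CC replicate 3) to 11604 in HH, 124 (without CC replicate 3) to 14507 in treated soil, 0 to 7 for HH against HC, 0 to 6 for HC against MC (both highest without HC replicate 1) and 0 to 4 for HH against MM. Beyond these, MC moved by over 1.5 times without CC replicate 2, MC replicates 2 and 3, MM replicates 1 and 2, HC replicates 1 and 2, and HH replicates 1 and 3. HC so moved without CC replicate 3, MC replicates 1 and 3, and any MM, HC or HH array but HH replicate 2. MM so moved without CC replicates 2 and 3, MC replicates 1 and 3, MM replicates 1 and 3, any HC array, and HH replicates 1 and 3. HH so moved without CC replicate 2 and HH replicates 1 and 3, treated soil without CC replicate 2, and HH against MM without CC replicate 1 and MC replicate 1.

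The biochar difference in listed probes ranged from 2512 (without MC replicate 1) to 5501, and its exact p reached 0.05 or more without MC replicate 1, any MM array and HC replicates 2 and 3 (highest 0.11). Categories past the test ranged from 0 to 3 for HC against MC (moved without MC replicate 3, MM replicate 3 and HH replicate 1), 1 to 6 for HH against MM (MM replicates 1 and 2, HH replicate 1) and 1 to 2 for biochar (MM replicate 2). Domains ranged from 3 to 5 in treated soil (CC replicate 1), 1 to 2 for HC against MC (MC replicates 1 and 3, HC replicates 2 and 3, any HH array) and 1 to 2 for HH against MM (HH replicate 1). Phyla ranged from 7 to 12 in treated soil (CC replicates 1 and 2) and 0 to 9 for HH against MM (MM replicates 1 and 2, HH replicates 2 and 3). Lists ranged from 0 to 1 in MC (CC replicate 2, MC replicate 1, MM replicate 3, HC replicate 1), HC (HC replicate 3), HH (HH replicate 1) and treated soil (CC replicate 3, MC replicate 1, HC replicate 2, HH replicates 2 and 3).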

Other observations

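Lineages read from the annotation shifted with treatment. Fungal genes held 2.88 ± 0.0517% of the signal in CC and 3.26 ± 0.0790% in HH (treated against control 0.11 ± 0.02 log2, limma adjusted p = 0.00124), with Ascomycota (0.10 ± 0.02) and Basidiomycota (0.12 ± 0.03) both higher and higher in HC than in MC (0.11 ± 0.03 and 0.14 ± 0.03). On probes listed on all 15 arrays no phylum passed for HC against MC. Actinobacteria fell from 26.7% to 25.2% in HH (-0.04 ± 0.01) but stood at 0.00 (0.005) on probes listed on all 15 arrays. Nitrospirae, a phylum with nitrite oxidizers, rose by 0.37 ± 0.04 log2 and Spirochaetes by 0.31 ± 0.05, and both passed on probes listed on all 15 arrays (0.16, limma adjusted p = 0.0196, and 0.11, limma adjusted p = 0.0235). Proteobacteria (51.7% in CC, -0.00 ± 0.01) and Acidobacteria (0.527%, 0.00 ± 0.02) did not pass. By limma 9 of 19 phyla rose and 2 fell, against 2 up and 0 down on probes listed on all 15 arrays.

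Between the rates with biochar, HH held more Bacteroidetes (0.14 ± 0.03 log2), Ascomycota (0.11 ± 0.03) and Nitrospirae (0.15 ± 0.05) than MM and less Actinobacteria (-0.05 ± 0.01), with 7 of 19 phyla up and 1 down by limma and 0 on probes listed on all 15 arrays. No phylum passed without MM replicate 2 or without HH replicate 2. HH and MM also differ in biochar dose. For biochar itself 0 phyla passed limma, with 5 at unadjusted p under 0.05. Archaea did not pass in treated against control soil (-0.00 ± 0.02 log2, limma adjusted p = 0.951).

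In Bray-Curtis dissimilarity MC replicate 1 lay nearest to CC replicate 1 (0.195) and then to MM replicate 3 (0.205), against 0.256 and 0.224 to MC replicates 2 and 3 and 0.272 and 0.230 to CC replicates 2 and 3. Whether this plot, its DNA or its array caused that was not tested.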
